A study of Mus musculus with 16 samples.

How the data were processed

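Liver RNA of 16 mice was sequenced, 1 library per mouse. Per the labels, the mice form 4 groups of 4, mature and immature, each with and without Cre. Animals with Cre are the liver-specific knockouts of oestrogen receptor alpha (LERKO), and those without are the floxed controls. The series title compares knockout before and after sexual maturity. Whether mature and immature describe the mice at knockout or at tissue collection is not given in the sources used here. Stage below means this label. The extraction protocol in the labels describes column-purified total RNA treated with DNase and stranded, paired-end mRNA libraries. Per the submitters' processing notes, mm10, STAR, R 4.05 and limma were used. Their roles, the counting program, the gene annotation, the settings for strand and shared reads, and the age and sex of the mice are not given in the sources used here.

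The deposited table holds 1 count per gene and library for 35502 genes, with no normalization visible in the values. In 5 columns the deposited values are best described as estimated counts, because 2 predicted genes hold 10 values that are not whole; these were rounded. All other deposited values are whole numbers, so the columns were treated as counts. The table gives 0 in every library for all 13 mitochondrially encoded genes, so that list could not be tested. The counts of Gm20425, which overlaps Trf on the same strand, were 94.8 to 95.5% of those of Trf in every library, so reads of overlapping genes were apparently entered for both, and the values of Trf, Hsp90b1 and Spp1, which each overlap another gene on the same strand, are uncertain to that extent. Reads of antisense partners cannot be told apart with the strand setting unknown; this concerns Btd, Fam84b, Eng, Ccnd1 and Xist, among others. Total counts ran from 18123974 to 23213905 per library, and 15853 to 16809 genes had at least 1 count.

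Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13379 genes; 15496 genes were at 0 everywhere. Counts were scaled by TMM factors (0.852 to 1.07) and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) in 1 model with a coefficient for each group, so that the groups share 1 estimate of the spread. P-values were adjusted over all tested genes by Benjamini-Hochberg, with a threshold of 0.05. If no gene differed, a share of about 0.05 of the genes would on average have an unadjusted p below 0.05. Standard errors of log2 fold changes were derived as the size of the fold change divided by the square root of its F statistic, and 95% intervals use the test's degrees of freedom. Levels are CPM, each count scaled to a common library total, after TMM scaling, given as mean ± SD over 4 libraries. The common biological coefficient of variation was 21.2%. Intervals of single genes cover the spread between mice of these groups.

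Before the data were examined, 31 gene lists were fixed, of which 28 had at least 5 tested members. They hold 699 distinct genes, 601 of them tested. Lists were tested on log2 CPM (prior count 2) with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stand camera with an estimated correlation and fry. The planned list tests cover both knockout comparisons and the comparison of stages in controls; those for the stages in LERKO and for the difference of knockout effects were added after the data were seen. The lists of pancreatic and adipose markers (4 tested genes) and of sex check genes (1) were too short to test.

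Genes were named by a rule fixed before the data were examined. Esr1 came first, then up to 10 genes in each direction past the threshold (5 for the difference of effects) with an average log2 CPM of at least 0 and no overlap between groups. Where no gene passed in a direction, the 3 with the smallest p under the same conditions were named and are said not to pass. From each list the 2 members with the highest mean level were available where no member passed. Values of some genes of the rule are not reported here. Genes outside this rule are said to be chosen after their values were seen. Positions are those of GENCODE vM21 on GRCm38, the assembly also called mm10; 35465 of the 35502 gene identifiers matched.

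Alternatives covered DESeq2, limma-voom with and without sample quality weights, RLE factors, library size alone, no filter, a filter of 1 CPM in 4 libraries, an adjusted p of 0.1, a log2 fold change of at least 1, the compared groups alone and each library left out. Settings chosen after the data were seen left out libraries in doubt, added a muscle covariate or used a robust fit. In simulated counts 200 genes were changed, and a further list of genes was raised 1.5-fold in the same group. Counts were drawn from the means and dispersions of these libraries without correlation between genes. For mature LERKO against control (13246 genes), 20.9% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 92.4% of those changed 4-fold were recovered. For the immature comparison (13266 genes) these shares were 23.9, 64.2 and 93.9%. More genes were changed in the simulation than passed in the real comparisons, which makes the adjusted threshold easier to reach. No library that stands apart from its group was simulated. The shares may therefore overstate recovery in the real data. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Replicate pairs were compared to find duplicate deposits of a library, over genes with a mean above 50 counts. The lowest chi-square per gene of a pair was 22.9 as a mean and 1.92 as a median, so no pair was counted as 1 library. Stage cannot be separated from cohort, since the animal numbers of mature and immature mice lie in separate ranges.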

Results

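The data are gene counts from the livers of 16 mice, 4 each of mature controls, mature LERKO mice, immature controls and immature LERKO mice. Esr1 encodes oestrogen receptor alpha, a hormone-activated transcription factor, and is deleted by design in the liver of LERKO mice. The protein was not measured here. Total counts per library ran from 18123974 to 23213905, and 13379 genes were tested. The comparisons ask how liver transcripts differ between LERKO and control mice within each labelled stage. They also ask how the stages differ in each genotype, and whether the knockout effect differs between stages. The stage labels may refer to the time of knockout or to that of tissue collection.

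Esr1 was lower in every LERKO library than in every control library of its stage. In mature mice it stood at 82.2 ± 19.1 CPM in controls and 16.3 ± 2.19 CPM in LERKO (SD, n = 4 each). In immature mice the levels were 73.6 ± 15.8 and 13 ± 2.19 CPM (SD, n = 4 each). Mature controls held 75, 66.7, 110 and 76.9 CPM and mature LERKO libraries 15.8, 19.1, 16.4 and 13.9 CPM. Immature controls held 65.8, 84.5, 89 and 55.3 CPM and immature LERKO libraries 10.7, 12.6, 16 and 12.7 CPM. The gene (ENSMUSG00000019768) lies on the forward strand of chromosome 10, from 4611593 to 5005614 of GRCm38. Which exon was deleted is not given in the sources used here, and counts over the whole gene include any transcript parts outside the deletion.

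**Figure D1:**
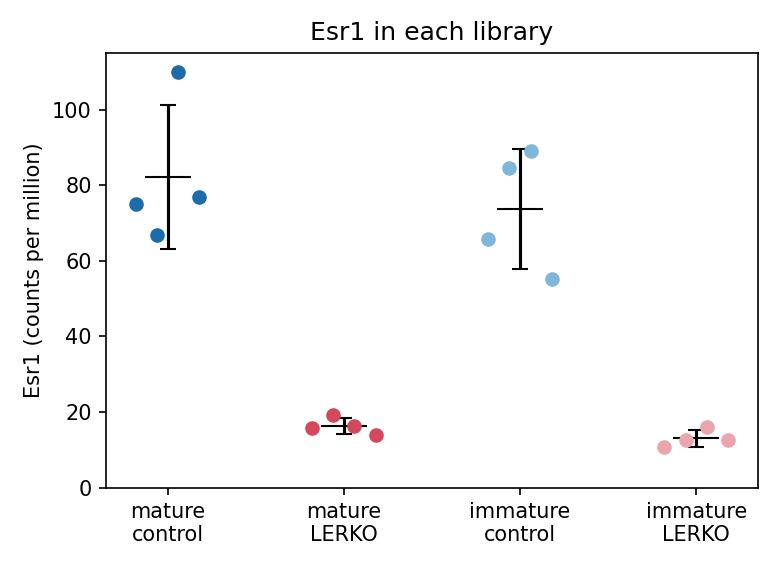
Esr1 in CPM (vertical axis) in each of the 4 groups of 4 libraries; points are libraries, the horizontal line is the mean and the whiskers are the SD. The highest LERKO library stands at 19.1 CPM and the lowest control at 55.3 CPM.

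In mature mice, Esr1 fell by 2.33 on the log2 scale in LERKO (SE 0.19, adjusted p = 1.57e-05, edgeR quasi-likelihood test), to 19.9% of control (95% interval 15.1 to 26.1%). No other gene passed. Btd, the enzyme that recycles biotin, stood at 65.1 ± 5 CPM in controls and 88.5 ± 7.04 CPM in LERKO, a log2 fold change of 0.44 (SE 0.10) that did not pass (adjusted p = 0.481, edgeR). Fam84b (20.9 ± 3.29 and 47.1 ± 19.8 CPM) and Lrfn3 (2.54 ± 0.787 and 5.02 ± 1.04 CPM) did not pass either, with the same adjusted p of 0.481 in edgeR.

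Among 28 tested gene lists, camera at the preset correlation called 9 in mature LERKO, 3 higher and 6 lower, and no member of any list passed over all genes. With an estimated correlation 0 were called (smallest adjusted p = 0.494), and with fry 0 (smallest adjusted p = 0.474). All 21 stellate cell and matrix markers had negative fold changes, with a median of -0.61 and an adjusted p of 0.494 with an estimated correlation. Bgn, a matrix proteoglycan, stood at 137 ± 16.3 CPM in controls and 90.3 ± 37.8 CPM in LERKO, and Ecm1 at 191 ± 21.2 and 136 ± 62.6 CPM. All 20 endothelial markers were negative too, with a median of -0.44 and an adjusted p of 0.527 with an estimated correlation. Eng, an endothelial TGF-beta co-receptor, stood at 65.3 ± 3.61 and 47.9 ± 20.8 CPM. Adjusted over the list alone, 0 stellate and 0 endothelial genes passed with edgeR, where 9 and 0 had an unadjusted p below 0.05. Library 4 of mature LERKO was the lowest of its group for Eng, at 17.6 CPM, and for Ecm1, at 44.4 CPM, and without it the medians were -0.33 for stellate and -0.19 for endothelial genes. Summed skeletal muscle transcripts differed alongside, at 945, 394, 2.01 and 71.1 CPM in the mature controls and at most 3.9 CPM in mature LERKO.

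Of 23 genes in the acute phase list, most of them for proteins that hepatocytes secrete in inflammation, 21 had positive fold changes in mature LERKO. Their median was 1.04, and the list had an adjusted p of 0.494 in camera with an estimated correlation. Adjusted over the list alone, 19 were higher and 0 lower, while 0 passed over all genes with edgeR. Fgb and Fga, fibrinogen chains, stood at 4310 ± 645 and 3890 ± 614 CPM in controls and at 7470 ± 5760 and 7150 ± 5180 CPM in LERKO. In library 4 of mature LERKO, Fgb reached 16100 CPM and the serum amyloid gene Saa1, chosen after its values were seen, 19000 CPM, against 25.5 to 94.4 CPM of Saa1 in the other mature LERKO libraries. Without that library the median of the list was 0.174 and 0 members passed adjusted over the list alone. Without mature control library 1 or 2, 7 members passed.

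Cell cycle genes had a median of -0.57 in mature LERKO, with 20 of 22 negative. Endoplasmic reticulum stress genes had a median of 0.45, with 17 of 20 positive and, adjusted over the list alone, 2 higher and 1 lower. Female-biased genes had a median of 0.31, with 2 of 23 higher adjusted over the list alone. Gluconeogenesis and glycolysis genes had a median of -0.2 and clock genes one of -0.24. Each of these 5 lists had an adjusted p of 0.494 with an estimated correlation. Pck1, the rate-limiting enzyme of gluconeogenesis, stood at 3550 ± 833 and 2430 ± 358 CPM. Of 75 nuclear-encoded respiratory chain subunits, 73 were negative, with a median of -0.09 and an adjusted p of 0.699 with an estimated correlation, and all 75 had a 95% interval within 2-fold. Atp5b, a subunit of ATP synthase, stood at 1110 ± 35 and 1040 ± 100 CPM. Single libraries moved these medians, to -0.24 for cell cycle and -0.15 for clock genes without mature control library 1, and to -0.14 for clock and 0.26 for endoplasmic reticulum stress genes without library 3 of mature LERKO. They were 0.1 for female-biased genes and -0.04 for respiratory chain genes without library 2 of mature LERKO, and -0.1 for gluconeogenesis without library 4. Adjusted over the list alone, 0 female-biased genes passed without mature control library 1, 3 or 4 or library 4 of mature LERKO. Of endoplasmic reticulum stress genes, 0 were higher without mature control library 1, 2 or 3, 8 without control library 4, and 13 and 9 without libraries 1 and 4 of mature LERKO. That count was 6 without immature control library 4 and 1 without library 2 or 3 of mature LERKO, immature control library 1 or 2, or library 1, 2 or 3 of immature LERKO.

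Camera did not call the oestrogen-responsive liver genes in mature LERKO, where 13 of 19 were positive, with a median of 0.16 and 0 passing adjusted over the list alone. Agt, the angiotensin precursor, stood at 876 ± 73.5 and 981 ± 40.3 CPM and the coagulation factor F12 at 547 ± 18.4 and 567 ± 62.4 CPM. Lipogenic genes had a median of -0.42 without a call, with Scd1, the stearoyl-CoA desaturase, at 7620 ± 1560 and 4970 ± 2190 CPM. Cholesterol synthesis genes had a median of -0.122 without a call, with 18 of 25 negative and 0 past adjusted over the list alone. Medians of 4 further metabolic lists were -0.01 for fatty acid oxidation, -0.03 for lipid droplets, -0.01 for bile acids and -0.04 for xenobiotic genes. For fatty acid oxidation the mean was of the other sign, and for lipid droplets and bile acids camera's direction was. At an unadjusted p below 0.05 there were 976 genes with edgeR, 7.3% of those tested. The count was 572 without mature control library 1 and 1516 without library 1 of mature LERKO. Without the 3 libraries with most muscle transcripts, a choice made after the data were seen, there were 360. These are mature control libraries 1 and 2 and library 4 of immature LERKO. Wherever they are left out, libraries 3 and 4 alone remain as mature controls, and library 4 still holds 71.1 CPM of muscle transcripts. Fewer libraries and less muscle cannot then be told apart. DESeq2 called 27, among them Btd, Fam84b, Lrfn3, Cacna2d1 and the muscle genes Myom2 and Myl3, the last 2 chosen after the calls were seen. The groups did not overlap for 3.9% of genes, against 2.86% by chance, and the 95% interval lay within 2-fold for 81.2%. Without library 1 of mature LERKO 2 genes passed, the second being Tgm1, chosen after its values were seen.

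In immature mice, Esr1 fell by 2.5 on the log2 scale in LERKO (SE 0.19, adjusted p = 6.55e-06, edgeR quasi-likelihood test), to 17.6% of control (95% interval 13.4 to 23.2%). No other gene passed. Col5a3, a fibrillar collagen chain, stood at 3.35 ± 0.694 CPM in controls and 8.95 ± 2.81 CPM in LERKO, a log2 fold change of 1.42 (SE 0.34) that did not pass (adjusted p = 1, edgeR). The DNA repair polymerase Polb (10 ± 1.47 and 13.3 ± 0.162 CPM) and the chromatin remodeller Hells (0.656 ± 0.023 and 1.55 ± 0.369 CPM) did not pass either.

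Camera at the preset correlation called 10 of 28 lists in immature LERKO, 6 higher and 4 lower. With an estimated correlation 0 were called (smallest adjusted p = 0.164), and with fry 0 (smallest adjusted p = 0.244). Of 22 cell cycle genes, 21 were positive, with a median of 0.85 and an adjusted p of 0.164 with an estimated correlation, and 1 was higher adjusted over the list alone, a count of 9 without mature control library 1 or library 3 of immature LERKO, 2 without library 3 of mature LERKO, 1 without immature control library 4 or library 1 of immature LERKO and 0 without any other. Pcna, the replication clamp, stood at 17.8 ± 1.27 and 21.1 ± 2.87 CPM, and Ccnd1, cyclin D1, at 123 ± 23.1 and 123 ± 31.9 CPM. All 20 lipogenic and all 25 cholesterol synthesis genes were positive, with medians of 0.72 and 0.37. Both lists had an adjusted p of 0.566 with an estimated correlation and 0 genes past adjusted over the list alone. Without library 4 of immature LERKO these medians were 0.03 and 0.01. Without immature control library 3 they were 1.25 and 0.98, with 10 and 18 genes higher adjusted over the list alone, and without control libraries 1 and 4 in turn the cholesterol median was 0.17 and 0.16. Scd1 stood at 2710 ± 2710 and 9080 ± 11100 CPM, with 25700 CPM in library 4 of immature LERKO, and Sc5d, an enzyme of cholesterol synthesis, at 435 ± 230 and 524 ± 243 CPM. Of 28 fatty acid oxidation genes, 26 were negative, with a median of -0.28, 0 past adjusted over the list alone and an adjusted p of 0.566 with an estimated correlation. Fabp1, the liver fatty acid binding protein, stood at 5560 ± 745 and 5120 ± 1900 CPM.

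Cholangiocyte (0.38), stellate (0.33) and endothelial lists (0.32) had positive medians in immature LERKO, with adjusted p-values of 0.366, 0.664 and 0.664 with an estimated correlation. Interferon genes (-0.12), endoplasmic reticulum stress genes (-0.17) and the growth hormone axis (-0.11) had negative medians, with adjusted p-values of 0.566, 0.664 and 0.566 with an estimated correlation. Adjusted over the list alone, 0 genes of these 6 lists passed. Library 4 of immature LERKO held 204 CPM of summed muscle transcripts, against at most 1.66 CPM in the other immature libraries. Without it the medians were 0.08 for stellate, 0.09 for endothelial, -0.02 for interferon, -0.11 for endoplasmic reticulum stress and -0.04 for growth hormone axis genes. Without immature control library 1 they were 0.17 for stellate, 0.25 for cholangiocyte, -0.05 for interferon and -0.03 for endoplasmic reticulum stress genes. Without library 1 of immature LERKO the growth hormone median was 0 and the interferon median -0.31, and without immature control library 3 they were -0.05 and -0.19. The endoplasmic reticulum stress median was -0.3 without immature control library 4, and -0.27 and -0.07 without libraries 2 and 3 of immature LERKO, where the interferon median was -0.07 without library 2. The acute phase median was -0.1 and that of oestrogen-responsive genes -0.07, neither called.

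At an unadjusted p below 0.05 there were 369 genes in the immature comparison with edgeR. That is 2.76% of those tested, a smaller share than chance alone gives on average. The count was 228 without control library 1, 675 without control library 3, 631 without LERKO library 1 or 3 and 207 without LERKO library 4. DESeq2 called 13, among them the muscle genes Acta1 and Ckm, chosen after their values were seen. The groups did not overlap for 1.63% of genes, against 2.86% by chance, and the 95% interval lay within 2-fold for 83.4%. Without the 3 libraries with most muscle transcripts, a choice made after the data were seen, 5 lists were called at the preset correlation.

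**Figure D2:**
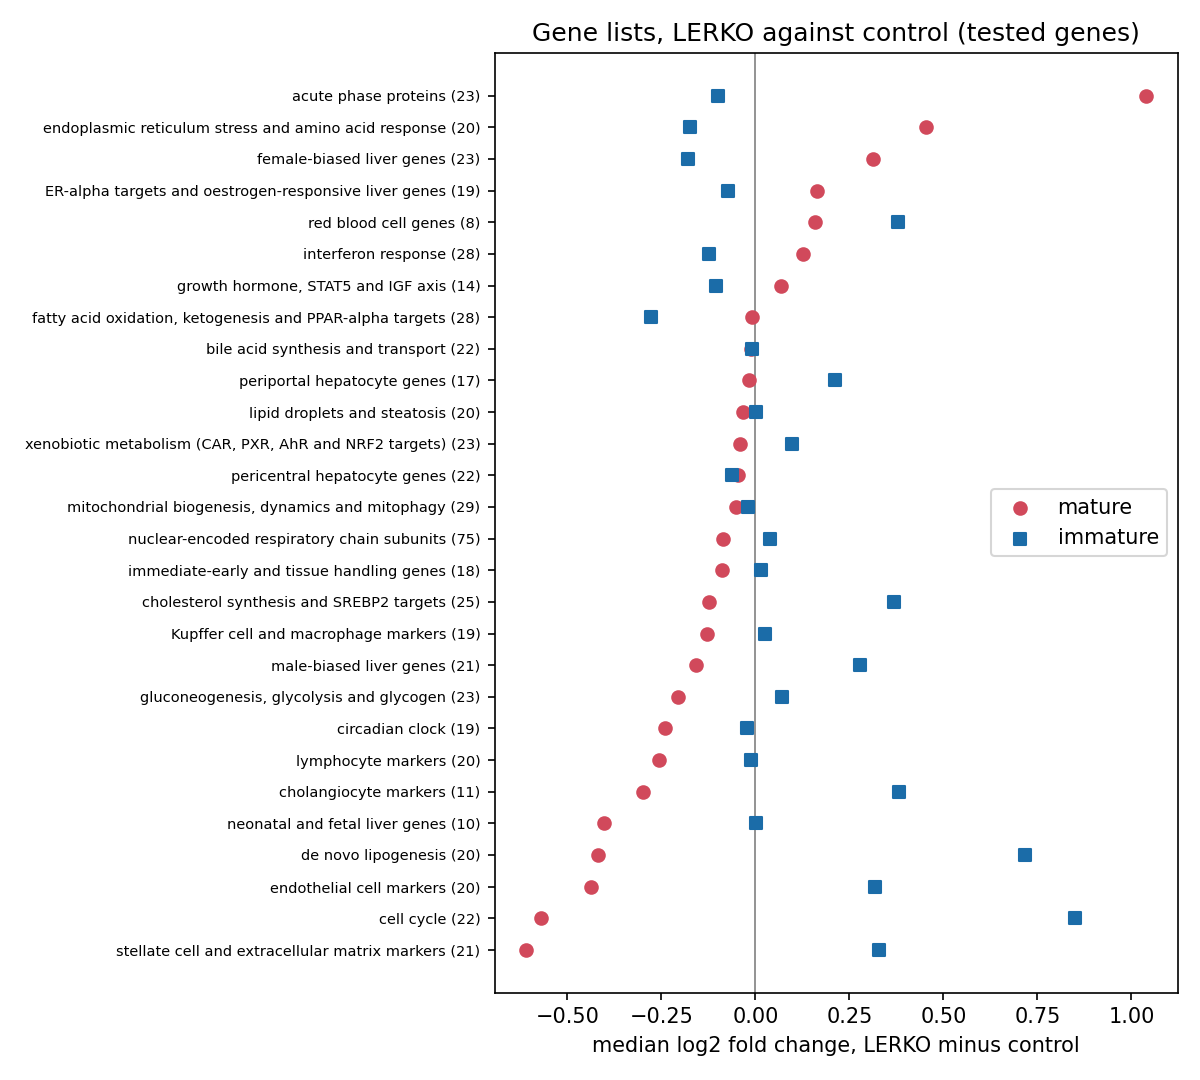
Median log2 fold change, LERKO minus control (horizontal axis), of the 28 tested lists (vertical axis, with the number of tested genes), in mature (circles) and immature mice (squares). The acute phase list stands at 1.04 in mature and -0.1 in immature mice.

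In control mice, mature against immature, 0 genes passed with edgeR. Tbl1xr1, a corepressor subunit, stood at 29.4 ± 1.18 CPM in mature and 45.4 ± 5.91 CPM in immature controls, a log2 fold change of -0.63 (SE 0.10) that did not pass (adjusted p = 0.129, edgeR). Tgfb1, a profibrotic cytokine, stood at 12.6 ± 1.26 and 6.82 ± 1.21 CPM, a log2 fold change of 0.89 (SE 0.17, adjusted p = 0.235, edgeR). Ppp1r9b (15 ± 2.34 and 9.53 ± 0.847 CPM), Cacna2d1, Proca1 and Zfp791 had that adjusted p in edgeR too.

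Camera at the preset correlation called 11 of 28 lists between the control stages, 6 higher and 5 lower in mature mice. With an estimated correlation 0 were called (smallest adjusted p = 0.512), and with fry 0 (smallest adjusted p = 0.147). Of 28 fatty acid oxidation genes, 27 had negative fold changes in mature controls, with a median of -0.46 and an adjusted p of 0.534 with an estimated correlation. Fabp1 stood at 4080 ± 435 and 5560 ± 745 CPM. All 22 cell cycle genes were positive, with a median of 0.63 and an adjusted p of 0.512 with an estimated correlation, and 5 were higher adjusted over the list alone. Tested for change in either direction with fry, this list passed (adjusted p = 0.0168), while in 1 direction with fry it did not (adjusted p = 0.147). Endothelial (0.7), stellate (0.59) and Kupffer cell lists (0.51) had positive medians, with adjusted p-values of 0.564, 0.564 and 0.534 with an estimated correlation. Adjusted over the list alone, 3, 3 and 6 of their members were higher. With single libraries left out these counts ran from 0 to 17, 1 to 18 and 0 to 12, each highest without library 4 of mature LERKO, which enters through the shared spread. They were lowest for endothelial genes without mature control library 1, 2 or 3 or immature control library 1, 3 or 4, for stellate genes without mature control library 1 or 2 or immature control library 1 or 4, and for Kupffer cell genes without control library 3 or 4 of either stage. Without mature control library 1 the cell cycle median was 0.38, with 2 members higher adjusted over the list alone, and without immature control libraries 2, 3 and 4 in turn 8, 3 and 2 were higher. For fatty acid oxidation 0 passed adjusted over the list alone, while 18 and 8 were lower without libraries 4 and 2 of mature LERKO, 17 and 16 without immature control libraries 2 and 3, and 14 without library 4 of immature LERKO. Clec4f, a Kupffer cell lectin, stood at 85.2 ± 9.95 and 61.8 ± 19.8 CPM. The muscle transcripts of mature controls, at 945, 394, 2.01 and 71.1 CPM, stood against at most 1.66 CPM in immature controls.

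Cholesterol synthesis (0.41) and lipogenic genes (0.43) had positive medians between the control stages, with adjusted p-values of 0.694 and 0.748 with an estimated correlation. Negative medians were those of lipid droplets (-0.3), endoplasmic reticulum stress (-0.2), oestrogen-responsive (-0.14) and respiratory chain genes (-0.08), with adjusted p-values of 0.569, 0.694, 0.512 and 0.806 with an estimated correlation. Adjusted over the list alone, 0 genes of these 6 lists passed. Without immature control library 3 the cholesterol and lipogenic medians were 0.87 each, with 14 and 1 members higher adjusted over the list alone. Without immature control library 1 they were 0.19 and 0.23 and the endoplasmic reticulum stress median -0.1, and without immature control library 4 they were 0.21 and 0.22, the lipid droplet median -0.13 and the respiratory chain median -0.04. The respiratory chain median was -0.12 and -0.05 without mature control libraries 2 and 4, and the oestrogen-responsive median -0.25 without mature control library 3. At an unadjusted p below 0.05 there were 1317 genes with edgeR, 9.84% of those tested. The count was 864 without mature control library 1 and 553 without the 3 libraries with most muscle transcripts. DESeq2 called 74, with Acta1 first, limma-voom 0, limma-voom with quality weights 8 and edgeR on the compared groups alone 6. The groups did not overlap for 8.86% of genes, against 2.86% by chance. Without library 4 of mature LERKO, which shares the spread estimate, 1 gene passed, Atp11a, chosen after its values were seen. Stage and cohort cannot be separated here.

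In LERKO mice, mature against immature, 0 genes passed with edgeR. Cyp2d9, a cytochrome P450 with higher levels in male liver, stood at 30.5 ± 12.4 CPM in mature and 85.4 ± 17.3 CPM in immature LERKO. Cxcl1, a neutrophil chemokine, stood at 46.6 ± 36.1 and 10.6 ± 3.31 CPM and the transcription factor Irf1 at 43.9 ± 7.39 and 27.5 ± 4.75 CPM. These genes, A1bg, Xkr9 and Slc25a28 had an adjusted p of 0.951 in edgeR. All 75 respiratory chain subunits had negative fold changes, with a median of -0.2, 6 with an unadjusted p below 0.05, 0 past adjusted over the list alone and an adjusted p of 0.407 with an estimated correlation. Without library 3 of immature LERKO that median was -0.07. Cholangiocyte markers had a median of -0.88, with 2 lower adjusted over the list alone and an adjusted p of 0.208 with an estimated correlation. Without library 4 of mature LERKO it was -0.54, and the count was 5 without library 1 of immature LERKO, 3 without library 2 or 3 of mature LERKO and 1 without library 1 of mature or library 2 or 3 of immature LERKO. The acute phase list had a median of 1.17, with 16 higher adjusted over the list alone and an adjusted p of 0.407 with an estimated correlation. The mean log2 level of the list was 10.6 in library 4 of mature LERKO and from 7.17 to 7.75 in the other LERKO libraries. Without that library the median was 0.06 and 0 members passed, and without library 4 of immature LERKO 7 passed. Camera called 15 of 28 lists at the preset correlation, 0 with an estimated one. At an unadjusted p below 0.05 there were 660 genes with edgeR, or 4.93%, about the share that chance alone gives. DESeq2 called 6 and limma-voom 0. The groups did not overlap for 1.52% of genes, against 2.86% by chance, and without library 1 of mature LERKO Tgm1 alone passed.

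For the difference of knockout effects, 0 genes passed with edgeR. For Esr1 the difference was 0.17 (SE 0.25, 95% interval -0.36 to 0.71, adjusted p = 0.928, edgeR). Tbl1xr1 had a log2 fold change of 0.33 in mature and -0.37 in immature LERKO, a difference of 0.7 (SE 0.14) that did not pass (adjusted p = 0.566, edgeR). Btd had 0.44 and -0.1, Sowahb 0.85 and -0.34 and Cacna2d1, a calcium channel subunit, -2.28 and 1.52, at the same adjusted p of 0.566 in edgeR. Cacna2d1 stood at 2.09 ± 1.46 CPM in mature controls and 0.949 ± 0.426 CPM in immature LERKO, the groups that hold the 3 libraries with most muscle transcripts. It stood at 0.418 ± 0.149 CPM in mature LERKO and 0.327 ± 0.198 CPM in immature controls. Whether muscle tissue accounts for its values was not tested. Dmbt1, a mucosal glycoprotein, stood at 6.59 ± 7.4 and 0.101 ± 0.124 CPM in mature control and LERKO mice and at 0.103 ± 0.207 and 27.5 ± 32.8 CPM in immature ones. At an unadjusted p below 0.05 there were 850 genes with edgeR, or 6.35% of those tested. DESeq2 called 22 and limma-voom 0. The DESeq2 calls, 1 higher and 21 lower, were headed by the muscle genes Tnnt3, Acta1, Myl3 and Myom2, chosen after the calls were seen. Cacna2d1 was also among them. Genes with an unadjusted p below 0.05 in edgeR numbered 462 without library 4 and 1280 without library 1 of immature LERKO. Without the 3 libraries with most muscle transcripts they numbered 197. On simulated counts this test recovered 52.2% of genes changed 2-fold among 13274 genes, a share that may overstate recovery in the real data.

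Esr1, the gene deleted by design in both comparisons, was the 1 gene that passed as lower at both stages with edgeR. The knockout comparisons of the stages share no library.

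**Figure D3:**
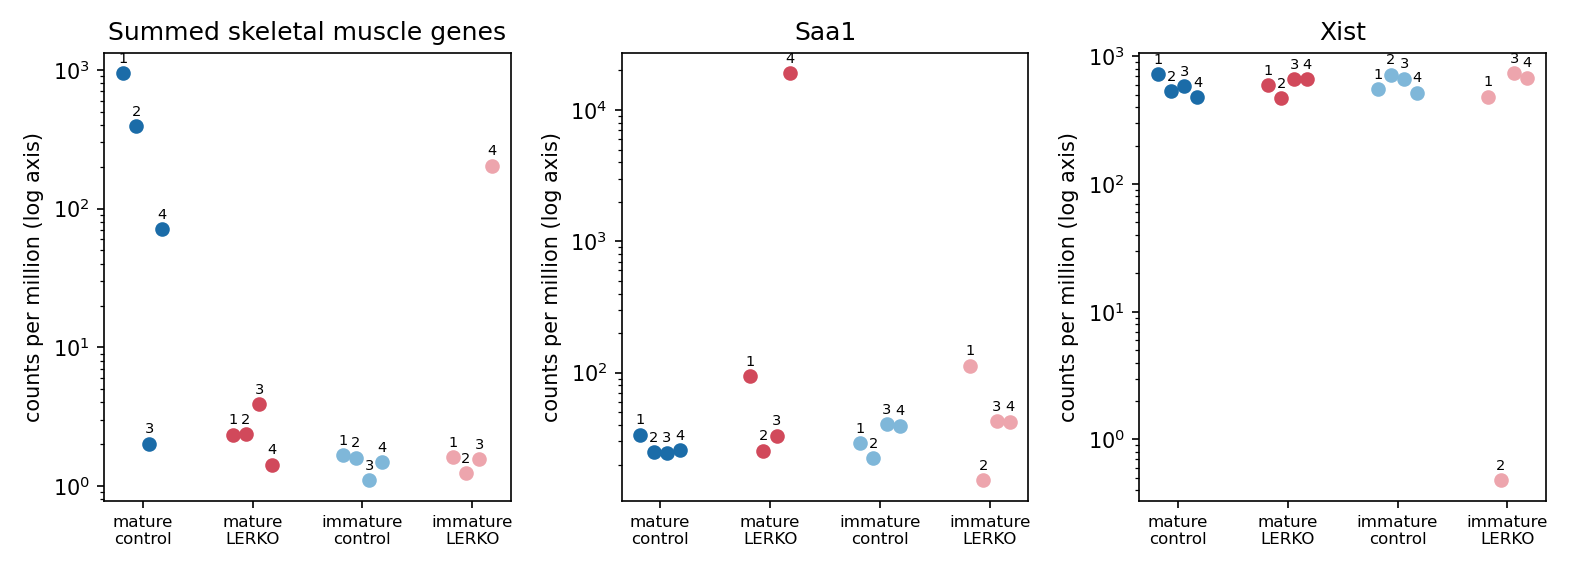
Summed CPM of skeletal muscle genes, Saa1 and Xist (vertical axes, logarithmic) in each library, numbered within its group. Muscle transcripts reach 71.1 CPM or more in 4 libraries, Saa1 reaches 19000 CPM in library 4 of mature LERKO, and Xist stands at 0.48 CPM in library 2 of immature LERKO.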

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

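The tests of single explanations below were chosen after the data were seen; the splits of the libraries were planned. Of 282 sets of 4 libraries examined, for gene levels on the log2 CPM scale and for measures of whole libraries, 33 had a library further from the others than Dixon's 95% critical value allows. Chance does this in about 1 in 20 sets. Saa1, Saa2, Lcn2, Trf, Acta1, Ckm, Tgm1, Atp11a and the summed muscle genes were chosen after their values were seen, so their 9 sets of this kind say nothing about an excess. Of the other 248 sets 24 were of this kind, against 12.4 by chance, and genes of 1 library are not independent. Some of these genes, such as Col5a3, Polb and Hells, were picked by the naming rule for their p in these same data. The chance rate need not hold for them, so these counts do not decide whether there is an excess. Library 4 of mature LERKO accounted for 8 of these 24 and library 4 of immature LERKO for 4. In library 4 of mature LERKO the ratio of gap to range was 0.973 for Trf, 0.907 for Atp5b, 0.893 for Atp11a, 0.863 for Lcn2, 0.86 for F12, 0.853 for Cps1, 0.852 for Ehd3, 0.843 for Ecm1, 0.841 for Eng and 0.833 for both Fgb and Clec4f. In library 4 of immature LERKO it was 1 for Acta1 and for Ckm, 0.947 for the summed muscle genes, 0.912 for Tnni2, 0.903 for Hells, 0.861 for Tgfb1 and 0.83 for Polb. Single libraries elsewhere stood apart for Col5a3 (0.963), Pck1 (0.853) and Saa1 (0.878) in mature controls, F12 (0.84) in mature controls, and Polb (0.853), Pck1 (0.875), Cyp2a4 (0.841), Scd1 (0.932) and Ckm (1) in mature LERKO. The same held for Cacna2d1 (0.842), Proca1 (0.89), Dmbt1 (1) and Ccnd1 (0.901) in immature controls and for Lcn2 (0.839) and Xist (0.941) in immature LERKO. A ratio of 1 is fixed wherever all libraries of a set but 1 are at 0, so the critical value does not apply there. The library apart held 46.2 CPM of Acta1 and 18.5 CPM of Ckm in immature LERKO. It held only 0.203 CPM of Ckm in mature LERKO and 0.413 CPM of Dmbt1 in immature controls, a set among the 24.

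The knockout effect on 16 lists differed between stages by camera at the preset correlation, a test added after the data were seen. The median difference was -1.28 for cell cycle, -1.13 for lipogenesis, -0.9 for stellate, -0.766 for cholangiocyte, -0.737 for endothelial, -0.582 for cholesterol synthesis, -0.479 for male-biased, -0.343 for gluconeogenesis, -0.126 for Kupffer cell and -0.116 for respiratory chain genes. It was 1.24 for acute phase, 0.564 for endoplasmic reticulum stress, 0.317 for female-biased, 0.297 for oestrogen-responsive, 0.285 for fatty acid oxidation and 0.238 for interferon genes. With an estimated correlation the adjusted p of these lists ran from 0.263 to 0.781. All 22 cell cycle genes had negative differences, and 12 were lower adjusted over the list alone. With fry the list did not pass in 1 direction (adjusted p = 0.0991) and passed for change in either direction (adjusted p = 0.0226). The count of 12 was 3 without mature control library 1 or library 3 of mature LERKO, 6 without library 2 of mature LERKO, 5 without immature control library 3 and 2 without immature control library 4 or library 4 of immature LERKO. Of 21 stellate genes 2 were lower adjusted over the list alone. That count was 7 without library 1 of immature LERKO, 1 without mature control library 2 or 3 or library 2 of mature LERKO, and 0 without mature control library 1, library 4 of mature LERKO, immature control library 1, 3 or 4, or library 4 of immature LERKO. Single libraries moved several of these medians. Without library 4 of immature LERKO they were -0.32 for lipogenesis and -0.11 for cholesterol synthesis, without library 2 of immature LERKO -0.06 for male-biased genes, and without library 3 of immature LERKO 0.01 for respiratory chain genes. Without library 4 of mature LERKO they were 0.25 for acute phase, -0.5 for cholangiocyte and 0.19 for oestrogen-responsive genes. The oestrogen-responsive median was 0.17 without library 3 of mature LERKO, and the cholesterol median -1.07 without immature control library 3. The male-biased median was -0.31 without mature control library 1 or immature control library 4 and -0.76 without immature control library 2. For fatty acid oxidation it was 0.17 without library 2 of mature LERKO, and 0.19 without immature control library 4 or library 4 of immature LERKO. The interferon median was 0.4 without library 1 of immature LERKO and the respiratory chain median -0.08 without library 2 of mature LERKO. The Kupffer cell median of -0.126 was -0.21 without mature control library 2, and -0.07, -0.04 and -0.32 without libraries 2, 3 and 4 of mature LERKO. Without immature control libraries 1 to 4 in turn it was -0.28, -0.27, 0 and -0.03, and without libraries 2 and 3 of immature LERKO -0.2 and -0.05.

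Other splits of the same libraries test the counts above 0. For mature LERKO against control, 2 of 35 splits gave as many genes as the real 1 (highest other 1), and for the immature comparison 4 of 35 (highest other 2), so chance was not excluded for the counts, although the other splits called other genes than Esr1. Of 100 drawn splits, 1, the real one, gave a gene called at both stages (highest other 0). That gene is Esr1, deleted by design at both stages, so the outcome was set by the design and decides nothing about chance. For lists called at the preset correlation, 26 of 35 splits reached the real 9 in mature LERKO (highest other 14), 16 of 35 the real 10 in immature LERKO (highest other 15) and 5 of 35 the real 11 between stages in controls (highest other 13), so chance was not excluded for any of the list counts. A count of 0 is reached by any split, so all 35 for the stages in controls (highest other 0) and in LERKO (highest other 55) and all 100 drawn ones for the difference of effects (highest other 2) decide nothing. The split with 55 genes, the highest of those for LERKO stages, of which 4 gave any gene, sets libraries 1 and 4 of both LERKO groups against libraries 2 and 3. A count so far above the real one points to a structure of these libraries, which was not tested further.

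The acute phase list had a positive median in mature LERKO, at 1.04. A rise above all mature controls in every mature LERKO library, with a rise in immature mice too, is argued against. Of the remaining mature LERKO libraries, 1 had a list score above all mature controls, and the immature median was -0.099. These values cannot exclude a smaller effect of the knockout or one in mature mice alone. Without library 4 the median was 0.174 (95% bootstrap interval over genes 0.154 to 0.323), so an acute phase response of 1 animal may account for most of the pattern. The interval reaches past the bound set for that explanation, which keeps open whether a smaller part lies in the other libraries. It does not cover the spread between mice.

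Stellate and endothelial lists had negative medians in mature LERKO, with a joint median of -0.544 over 41 genes. The medians of 5 lists of other cell types spread over 0.482, from -0.61 for stellate to -0.128 for Kupffer cell genes, but over mice the mean log2 level of Kupffer minus that of stellate genes was higher by 0.59 in LERKO than in control, without passing (exact permutation test, two-sided p = 0.429 over 70 assignments), and without library 4 of mature LERKO their medians were -0.333 and -0.336, with a spread over the 5 lists of 0.311. Without the 3 libraries with most muscle transcripts the joint median was -0.415 (interval -0.491 to -0.389), and without the acute phase library it was -0.241 (interval -0.303 to -0.196). A different share of hepatocytes, muscle tissue and the acute phase library may each contribute, and how much cannot be told apart: the difference of that pair rests on 1 library, the first interval crosses the bound above which muscle would be argued against, with its median just past that bound, and the second interval lies between its bounds. A knockout effect on these cells stays open, as untested.

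Xist was almost missing in library 2 of immature LERKO, with 9 counts or 0.48 CPM against 469 CPM or more elsewhere. The highest count over the Y-linked genes was 0, below the level set for a male animal. Y-linked counts were 0 in every other library too, so nothing shows that this table can report them. A male animal is therefore not excluded. Activity of both X chromosomes is argued against by X-linked genes outside the escape group, which differed from autosomal genes by -0.032, within the range of the other libraries (-0.034 to 0.068). A single X chromosome is a candidate explanation. The median log2 ratio of Kdm6a, Eif2s3x, Kdm5c and Ddx3x, which escape X inactivation, was -0.644, against -0.122 to 0.252 in the other libraries. Ddx3x alone (172 CPM), however, lay within their range. A male animal would also carry a single X, so these values do not separate a male from a female with a single X. No biological explanation from the design was tested, and the karyotype was not measured.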

How the results depend on the processing

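Of 241 counts recomputed under alternatives, 51 differed from the first value, 19 of them by over 1.5 times or to or from 0; the libraries in doubt, the muscle covariate and the robust fit were chosen after the data were seen. Esr1 kept its direction and call throughout, from -2.54 to -2.16 in mature mice (highest adjusted p 0.00363) and from -2.62 to -2.4 in immature mice (0.00779). DESeq2 called 27 genes in mature and 13 in immature LERKO, 74 and 6 between stages in controls and LERKO, and 22 for the difference of effects. Muscle genes, among them Acta1, Tnnt3, Atp2a1, Mybpc1 and Ckm, were prominent among its calls with the smallest adjusted p. This held in the immature comparison, between stages in controls and for the difference of effects, and these genes were chosen after the calls were seen. Why DESeq2 called more genes than edgeR was not tested. Between stages in controls, quality weights gave 8 genes and the compared groups alone 6. Leaving out single libraries gave 1 to 2 genes in mature LERKO, 0 to 1 between stages in controls and in LERKO. Without mature LERKO library 1, Tgm1 was added to the mature knockout and the LERKO stage comparison, and without mature LERKO library 4, Atp11a was called between stages in controls; both genes were chosen after their values were seen. Lists called at the preset correlation fell to 0 in all 3 comparisons with an estimated correlation and with fry. Leaving out single libraries gave 8 to 11 lists in mature LERKO, 7 to 13 in immature LERKO and 8 to 13 between stages. Without the 3 libraries with most muscle transcripts 5 lists were left in immature LERKO, and without the 5 libraries in doubt 5 in mature and 5 in immature LERKO. Medians of called lists without each library in turn were computed after the data were seen. Precision was lower for genes of low level: in mature LERKO against control the interval lay within 1.5-fold for 18.7% of the 4460 genes with the lowest mean level (median SE 0.3) and for 81.3% of the 4460 with the highest (0.13). Whether more depth would narrow it was not tested.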

Other observations

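Across 13378 genes other than Esr1, the fold changes of the knockout in mature and in immature mice had a Pearson correlation of -0.627 and a Spearman correlation of -0.166, and 45.3% had the same sign. The comparison is across genes, which are not independent replicates, and the comparisons share no library. Muscle transcripts, present in 3 mature controls and in library 4 of immature LERKO, take opposite signs in these comparisons: Acta1, chosen after its values were seen, stood at 65.9 ± 75.8 CPM in mature controls and 11.6 ± 23.1 CPM in immature LERKO, and at or near 0 in the other groups.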
